A study of Mus musculus with 2 samples.

How the data were processed

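Lung cells that had been flow-sorted as CD45.2-negative, a gate that takes out most blood-derived cells, were measured by droplet 3' single-cell RNA sequencing in 2 libraries, 1 from wild-type (WT) mice and 1 from mice labelled Plaur KO. Per the labels about 16000 live cells were loaded for an aim of 10000. The labels do not say how many of the 8 mice per genotype each library held, and they call the material total lung cell lysate. The deposited matrices hold counts, that is raw UMI counts per gene and barcode without normalization, and the authors wrote them with Cell Ranger (versions 7.0.0 and 7.1.0 per the submitters' processing notes; the file headers give 7.0.0). How barcodes were chosen before deposit and whether intronic reads were used is not stated.

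Cells with at least 500 genes and at most 15% mitochondrial UMIs were kept. Scrublet in scanpy 1.11.5 was run on each library with an expected share of 8%, and the cells it marked as doublets were removed: 617 (5.69%) in the WT library and 175 (1.92%) in the KO-labelled library. Both libraries were clustered together without integration on 2000 highly variable genes, 30 principal components and 15 neighbours with Leiden resolution 1 (leidenalg 0.10.2). Plaur, mitochondrial, ribosomal, haemoglobin and sex-linked genes did not shape the clusters. A cluster took the name of a cell class when at least 3 of that class's preset markers were among its 50 leading genes and no other class or compartment led. The leading genes were ranked by fold over the median cluster, with 10 CPM added, among genes seen in at least 20% of the cluster's cells. The form of this fold was chosen after the clusters were seen and before any gene ratio was computed. Clusters under 20 cells were not named. Of 33 clusters, 28 were named, into 18 classes. A fibroblast cluster with mixed fibroblast markers is compared by its number, cluster 6.

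UMIs were summed per library and class and divided by the class total, on the usual CPM scale. Each log2 ratio is the KO-labelled library over the WT library, with an exact conditional binomial 95% interval. Shares have exact Clopper-Pearson intervals and CPM values exact Poisson intervals. A gene with no UMI in 1 library stands at a floor of 3 UMIs. All intervals cover counting error only. With 1 library per genotype there is no replicate check on any difference, and no test, p-value or standard error was computed. Classes with at least 100 cells in each library were compared. Classes with 20 cells or more in each library were added after the data were seen. The fibroblast cluster compared by its number did not meet the naming rule for a class. This cluster could be picked out for comparison only after the clusters were seen, and it counts among the compared classes throughout. The other choices above were fixed before the data were examined.

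A gene list needed 5 members with at least 20 UMIs over both libraries. Its value is the median log2 ratio of its members minus the median of all genes with 20 UMIs in the class. The percentile of that value among 10000 random lists matched on mean CPM in 20 bins is a description of these libraries. Intervals of list values come from 1000 Poisson draws. Named genes followed a preset rule. These are Plaur, then the 4 highest and 4 lowest members of each primary list in its class with a fixed set of allergy and contraction genes. In each compared class come the 5 genes highest in each library (3 in classes with under 500 cells in either library) that had at least 100 UMIs and 50 CPM in the higher library. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and sex-linked genes, genes without a proper symbol and genes over 10 times higher in a class of another compartment were left out of that last step. Sex-linked and free-RNA marker genes are given as checks. The rule also held Nnt as a check of strain background, whose values are not given here, so the strain of the libraries was not compared. Genes named outside the rule are marked as chosen after their values were seen.

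Gene positions are from GENCODE mouse release M21 (GRCm38), in which 32158 of the 32285 gene identifiers were found. Alternatives covered looser and stricter cell filters, doublets kept, other resolutions, libraries clustered apart, edgeR 4.0.16 TMM factors, the 50 most abundant genes left out of totals, cells thinned to 1000 UMIs, means over cells, other low-count filters and list means. TMM scaling would move all ratios by 0.12 in AT2-like cells, 0.26 in airway secretory-like cells, -0.27 in neutrophil-like cells and 0.25 in all cells together. In the other compared classes the move lay between -0.04 and 0.06.

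The procedure was tested on simulated data with the depth of 3 classes, WT against KO-labelled, with 200 genes set to a log2 ratio of 1 in either direction. The 95% intervals held the true ratio for 95.7% of 13831 genes in AT2-like cells, 96.1% of 8984 genes in adventitial fibroblast-like cells and 96.4% of 5602 genes in venous-like cells. Among the set genes with at least 100 UMIs, the interval lay beyond 0 on the right side for 100.0% of 167, 90.8% of 87 and 96.5% of 57 genes in the same order. The simulation has counting error alone and says nothing about variation between mice. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.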

Results

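Structural cells of the lung were profiled after allergen challenge in WT (C57B6/J) mice and in mice labelled as lacking Plaur, the gene of the urokinase receptor uPAR. The mice had been sensitised with lipopolysaccharide and ovalbumin on days 0 and 7 and challenged with ovalbumin aerosol on day 14. The question named by the series is how uPAR bears on eosinophil migration and airway reactivity. There were 2 libraries, 1 per genotype. The WT library held 11776 barcodes and 57028943 UMIs, the KO-labelled library 9771 barcodes and 51529241 UMIs. After filtering, 10225 and 8934 cells remained, with medians of 4837 and 5538 UMIs and of 1909 and 1963 genes per cell. No difference below has a replicate check.

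Plaur mRNA was counted in both libraries, so the transcript level does not show the knockout. Its direction depended on the cell class: aerocyte-like, mesothelial-like and fibroblast-like cells had less Plaur in the KO-labelled library, and AT2-like, ciliated-like, venous-like and general capillary-like cells had more. Plaur (ENSMUSG00000046223) lies on chromosome 7 from 24462484 to 24475968 and has 7 exons, with the 3' untranslated region at 24475469 to 24475967. The assay reads the 3' end, and the labels do not say which part was deleted, so a 3' tag outside the deleted part checks nothing about the protein. For this reason the second library is called KO-labelled throughout, and every direction below rests on that label.

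Over all kept cells Plaur stood at 46.95 CPM in the WT library (2374 UMIs) and 33.1 CPM in the KO-labelled library (1634 UMIs), a log2 ratio of -0.51 (95% interval -0.60 to -0.42). The mean of the log2 ratios of the compared classes, each class weighted equally, was 0.40, on the other side of 0. In aerocyte-like cells, the capillary cells specialised for gas exchange, Plaur was 475 against 240.1 CPM (log2 ratio -0.98, -1.23 to -0.74). Mesothelial-like cells had 152 against 84.2 CPM (-0.85, -1.15 to -0.56). Cluster 6 had 89.3 against 59.4 CPM (-0.59, -1.03 to -0.16). Adventitial fibroblast-like cells had 70.2 against 39.5 CPM (-0.83, -1.61 to -0.13), which turned to 0.19 when cells were thinned to 1000 UMIs. In AT2-like cells, the surfactant-making cells, Plaur was 2.22 against 17.6 CPM (2.98, 2.59 to 3.41). Ciliated-like cells had 12.3 against 46.2 CPM (1.91, 1.50 to 2.33), venous-like cells 55.6 against 119 CPM (1.09, 0.30 to 1.91), and general capillary-like cells 115 against 158 CPM (0.46, 0.18 to 0.74). Neutrophil-like cells, a class of 145 and 25 cells, had the highest level in the WT library, 1781 against 979 CPM (-0.86, -1.33 to -0.43).

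**Figure D1:**
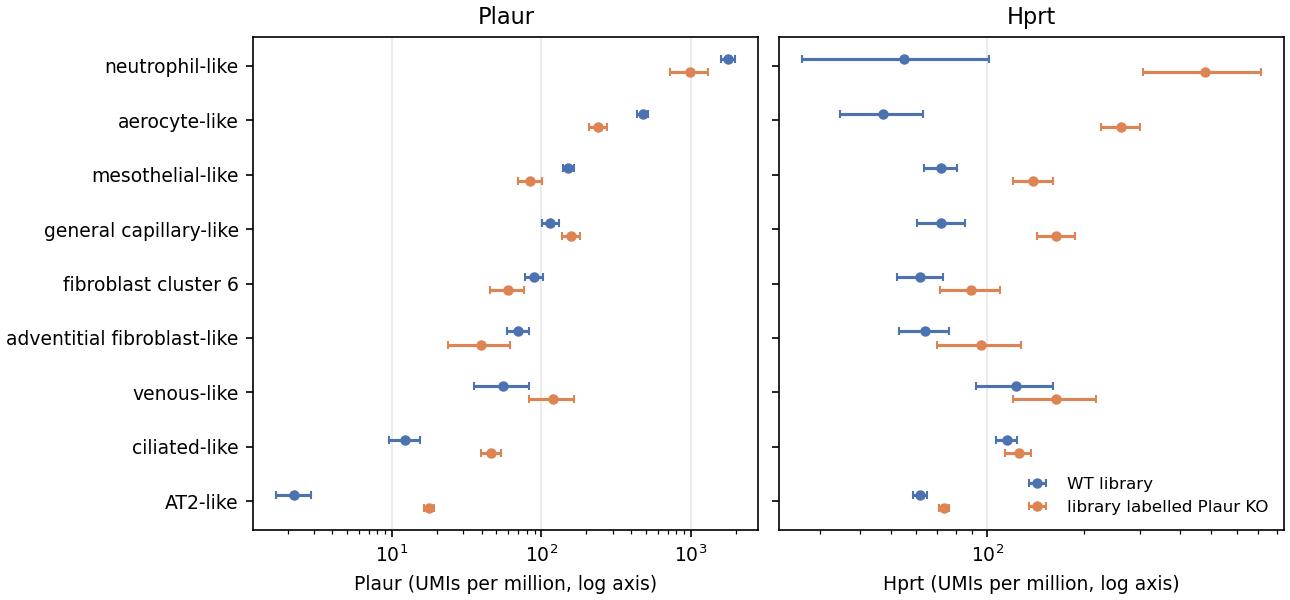
Plaur and Hprt in CPM (log axis) for 9 cell classes, WT library in blue and KO-labelled library in orange, with exact Poisson 95% intervals. Plaur in AT2-like cells was 2.22 against 17.6 CPM and in aerocyte-like cells 475 against 240.1 CPM, while Hprt in aerocyte-like cells was 47.4 against 261 CPM.

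The mix of cells differed between the libraries. Epithelial cells made up 51.0% (50.1 to 52.0) of kept cells in the WT library and 73.4% (72.5 to 74.3) in the KO-labelled library. The shares of mesenchymal, mesothelial and immune cells were lower in the KO-labelled library. All shares describe CD45.2-negative sorted cells after removal of marked doublets. Endothelial cells were 20.8% against 15.7% (log2 ratio -0.40, -0.50 to -0.31), mesenchymal cells 12.9% against 5.45% (-1.24, -1.39 to -1.09), mesothelial cells 8.41% against 2.89% (-1.54, -1.75 to -1.34) and immune cells 5.06% against 1.51% (-1.74, -2.03 to -1.47). AT2-like cells alone were 37.3% against 65.1%, and adventitial fibroblast-like cells 4.35% against 1.20%. Airway secretory-like cells were 3.48% against 1.11%, ciliated-like cells 9.37% against 6.55%, and neutrophil-like cells 1.42% against 0.28%. AT1-like cells were few, 15 and 42. Shares sum to a fixed total, so they do not tell more AT2-like cells from fewer cells of other classes.

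**Figure D2:**
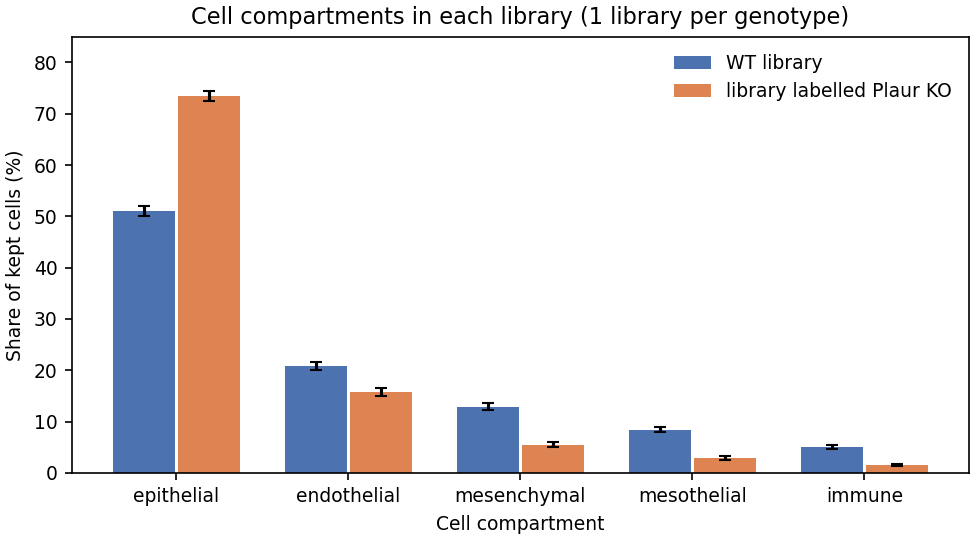
Share of kept cells (%) in each of 5 compartments, WT library in blue and KO-labelled library in orange, with exact Clopper-Pearson 95% intervals and 1 library per genotype. Epithelial cells were 51.0% against 73.4%, and each of the other 4 compartments had a lower share in the KO-labelled library.

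Adventitial fibroblast-like cells, which surround airways and vessels, carried much of the chemokine message in both libraries. Ccl11, which encodes eotaxin-1, a chemokine that draws eosinophils, was higher in the KO-labelled library, as were Ccl8, Cxcl12 and the alarmin Il33. The adhesion gene Icam1 and the matricellular gene Postn were lower. Ccl11 (ENSMUSG00000020676, chromosome 11, 82057823 to 82062955) was 2931 against 3874 CPM (log2 ratio 0.40, 0.33 to 0.48), and Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718) 883 against 1115 CPM (0.34, 0.19 to 0.48). Ccl8 was 218 against 303 CPM (0.47, 0.19 to 0.75). Icam1 was 315 against 226 CPM (-0.47, -0.78 to -0.18) and Postn 121 against 70.6 CPM (-0.78, -1.34 to -0.26). The list of eosinophil recruitment genes as a whole had a median of -0.11 (percentile 10.5), with 5 of 14 members above the class median, and this median was 0.04 in thinned cells.

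Matrix genes in adventitial fibroblast-like cells went both ways. The collagen gene Col1a1 (2735 against 3822 CPM; 0.48, 0.41 to 0.56), Sparc, Mfap4, the protease gene Mmp3 (474 against 1020 CPM; 1.11, 0.94 to 1.27) and its inhibitor Timp1 were higher in the KO-labelled library. Ltbp1, Adamts5 and Adamts4 were lower. The matrix list median was 0.06 (percentile 93.9) in adventitial and 0.22 (percentile 97.55) in alveolar fibroblast-like cells, a class of 188 and 71 cells; the first became -0.01 with TMM scaling and no centring. In the plasminogen system, Plau, the gene of the uPAR ligand, had 25 and 2 UMIs in adventitial fibroblast-like cells, with an interval that included 0. The plasminogen list stood at 0.03 in adventitial and 0.14 in alveolar fibroblast-like cells. Outside these lists, Apoe, the stress gene Herpud1 and Ccn2 were highest in the KO-labelled library (log2 ratios 1.40, 1.38 and 1.33). Nr4a3, Rabgef1 and the hyaluronan synthase gene Has1 were lowest, with Has1 at 666 against 181 CPM (-1.88, -2.21 to -1.57).

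Monocyte chemokine genes differed between the other fibroblast-like classes. In alveolar fibroblast-like cells Ccl2 was 2086 against 910.3 CPM (-1.20, -1.48 to -0.92) and Ccl7 420 against 149 CPM (-1.49, -2.24 to -0.82). The recruitment list median there was -0.31 (percentile 2.74), and -1.21 in thinned cells. In cluster 6 Ccl2 was higher (2105 against 2766 CPM; 0.39, 0.33 to 0.46) and Ccl7 lower (1365 against 1052 CPM; -0.38, -0.48 to -0.27), both chosen after their values were seen, and the list median was -0.13 with an interval that included 0. Targets of NF-kB, the inflammatory transcription factor, had medians of -0.66 in cluster 6 and -0.41 in adventitial fibroblast-like cells, but -0.08 (percentile 15.2) in alveolar fibroblast-like cells.

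Venous-like endothelial cells, where leukocytes leave the blood, had less message of adhesion genes in the KO-labelled library. Vcam1, which eosinophils bind through an integrin, and the selectin genes Selp and Sele were lower, as was the chemokine-transporting receptor gene Ackr1. Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688) was 4717 against 2788 CPM (log2 ratio -0.76, -0.88 to -0.64), and Selp 1919 against 901 CPM (-1.09, -1.298 to -0.887). Sele was 269 against 143 CPM (-0.91, -1.46 to -0.38). Ackr1 was 318 against 87.3 CPM (-1.86, -2.54 to -1.24). The adhesion and barrier list had a median of -0.30 (percentile 0.03), with 19 of 26 members below the class median. The recruitment list had -0.31 (percentile 1.19), but 0.02 when each library was clustered apart. Kirrel3 and Colec12 were also among the lowest, and Thbs1, Serpinb1a and the chaperone gene Hspa5 were highest in the KO-labelled library. This class of 198 and 109 cells was not clean in the KO-labelled library, since Sftpc, an AT2 gene, was 1124 against 17497 CPM and Scgb1a1, an airway secretory gene, 1534 against 33744 CPM. Such RNA lowers the CPM of endothelial genes, in the same direction as the adhesion values. The random lists were matched on CPM and not on cell type, so the low percentile does not set this apart.

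**Figure D3:**
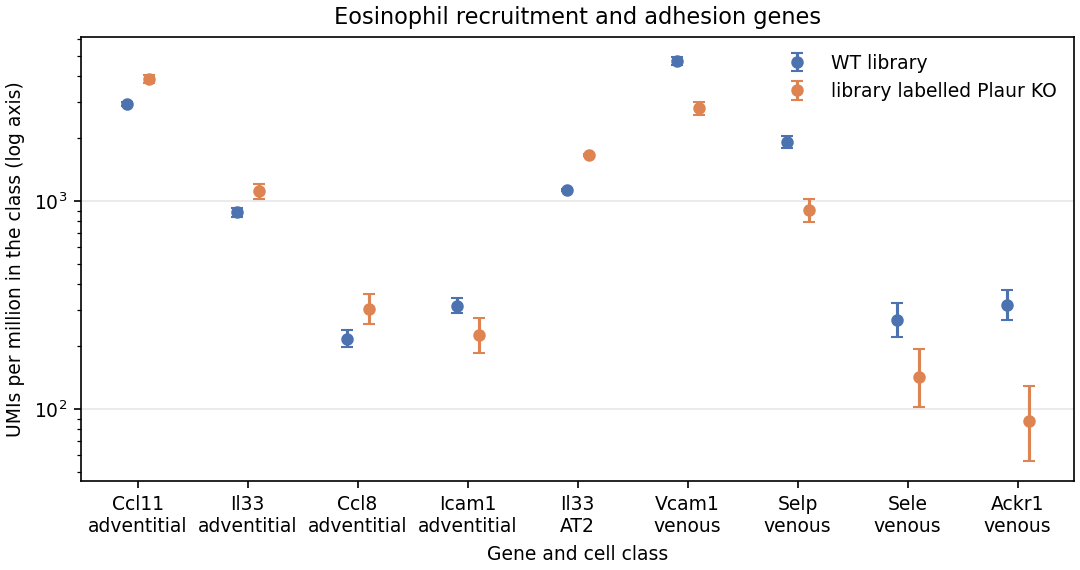
CPM (log axis) of genes of eosinophil recruitment and adhesion in adventitial fibroblast-like, AT2-like and venous-like cells, WT library in blue and KO-labelled library in orange, with exact Poisson 95% intervals. Ccl11 in adventitial fibroblast-like cells was 2931 against 3874 CPM, and Vcam1 in venous-like cells 4717 against 2788 CPM.

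The adhesion and barrier list had medians of 0.01 in both general capillary-like and aerocyte-like cells. Members went both ways in general capillary-like cells, with 14 above and 13 below the class median, and their mean was -0.15. Tight-junction gene Cldn5 in general capillary-like cells was 3541 against 4356 CPM (0.30, 0.25 to 0.35), while the selectin gene Selp was lower there too (-1.32, -2.09 to -0.61). Plat, the gene of tissue plasminogen activator, was 36.7 against 71.9 CPM in general capillary-like cells (0.97, 0.50 to 1.44), and the plasminogen list, which includes Plaur, had a median of 0.29 (percentile 99.78) that was 0.12 with libraries clustered apart. The largest log2 ratio among the named genes of this class was that of Cyp26b1 (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908), which encodes an enzyme that breaks down retinoic acid, at 18.6 against 152 CPM (3.026, 2.501 to 3.59). Tmem252, Hprt (71.9 against 164 CPM) and the glucocorticoid-induced genes Zbtb16 and Tsc22d3 followed (1.21, 1.19, 1.19 and 1.15). Filip1, Cirbp, Pir, Ripk2 and Gna14 were lowest. The circadian and glucocorticoid list lay above the class median in each compared class, from 0.09 in ciliated-like to 0.62 in general capillary-like cells. Its interval included 0 in ciliated-like, adventitial fibroblast-like and mesothelial-like cells. In aerocyte-like cells Hprt and the chaperone genes Hspa8 and Dnaja1 were highest (2.46, 1.35 and 1.05), and Kif26b, the bradykinin receptor gene Bdkrb2 and Mllt3 lowest (-1.49, -1.28 and -1.20). Hprt (ENSMUSG00000025630, chromosome X, 52988137 to 53021659), a purine salvage gene, was 47.4 against 261 CPM in aerocyte-like cells.

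AT2-like cells had more Il33 in the KO-labelled library and slightly more message of surfactant and lipid genes. Il33 was 1131 against 1662 CPM (log2 ratio 0.56, 0.54 to 0.58). The surfactant and lipid list had a median of 0.16 (percentile 99.99), with 18 of 23 members above the class median, among them Sqle, Hmgcs1 and Sftpd, while Elovl1 was lower (-0.53, -0.56 to -0.50). The cholesterol synthesis list stood at 0.58, with 17 of 17 members above. That list was also above the class median in venous-like (1.23) and mesothelial-like cells (0.72) and in cluster 6 (0.65). It was 0.06 in ciliated-like and -0.04 in adventitial fibroblast-like cells, with intervals that included 0. Scaled by Sftpc, extra free RNA from AT2-like cells was 9.86% in venous-like cells, 3.23% in mesothelial-like cells, 2.62% in cluster 6 and 3.20% in ciliated-like cells. Its part in the cholesterol values was not tested. In AT2-like cells Pglyrp1, an antibacterial gene, was 26.7 against 112 CPM (2.07, 1.96 to 2.19). Retnla, a gene induced by IL-4 and IL-13, was 1641 against 3930.3 CPM (1.26, 1.25 to 1.28). Cmss1, Ide and Zbtb16 came next. The stress cytokine gene Gdf15 was 58.5 against 17.8 CPM (-1.71, -1.85 to -1.58), and Ccl20, a chemokine gene, 110 against 35.8 CPM (-1.62, -1.71 to -1.52). Cirbp, Adamts1 and Naaladl2 were also lower. The eosinophil recruitment list had a median of -0.89 (percentile 0.0), but 7 of its 12 measured members were over 10 times higher in a class of another compartment. Without these 7 the median was -0.20, with Icam1 (-0.31), Anxa1 (-0.36) and Lgals9 (-0.28) lower. The list gave -0.26 in thinned cells, -0.24 with a minimum of 100 UMIs and -2.47 with libraries clustered apart.

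Airway cells were fewer, with 356 and 99 airway secretory-like cells. Muc5ac (ENSMUSG00000037974, chromosome 7, 141788972 to 141819231), which encodes the inducible airway mucin, had 82 and 4 UMIs (20.1 against 2.71 CPM; -2.89, -4.80 to -1.48). Agr2, needed for mucin folding, was 48.5 against 9.48 CPM (-2.35), Itln1 20.1 against 4.06 CPM (-2.31) and Bpifb1 663 against 312 CPM (-1.09). Retnla was 8009 against 11740.3 CPM (0.55, 0.53 to 0.58). The IL-4 and IL-13 response list had a median of -0.37 (percentile 0.01), with 15 of 22 members below the class median. It was -0.051 with means over cells. In cells thinned to 1000 UMIs it was 0.20, and Muc5ac and Itln1 were 0.26 and 0.85. Both gene values match a gene with no UMI in the KO-labelled library, set to the floor of 3 UMIs. They are then upper bounds and do not show a higher level. The recruitment list had -0.73 in this class, with 7 of 8 members over 10 times higher in another compartment. In ciliated-like cells the chaperone genes Hspb1 (290.1 against 832 CPM; 1.52) and Dnaja1 (1.23) were higher. The other genes highest in ciliated-like cells, Hc, Sftpb and Scd1, are AT2 genes, and Scgb3a1, Sult1d1, Reg3g and Aoc1, among the lowest, are genes of secretory cells; Wdr95 was lower as well.

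Smooth muscle-like cells, the contractile cells of airways and vessels, numbered 88 and 35. Acta2 was 10991 against 9252 CPM (-0.25, -0.35 to -0.15) and Myh11 2243 against 2039 CPM, within counting error. Tpm1, Vcl, Myocd and Actn1 were lower, and Ednra, Cacna1c, Mylk and Prkg1 were higher with intervals that included 0. The contraction list had a median of -0.17 (percentile 12.9), which was 0.05 in thinned cells. Il33 had 21 and 65 UMIs in this class (3.003, 2.27 to 3.79), but Sftpc of AT2-like cells, which also have Il33, was higher there too, at 9697 against 34946 CPM. AT2 transcripts take up part of the class total, which lowers the CPM of muscle genes. How much of the lower Acta2 this accounts for was not tested. In the same class the recruitment list had a median of -0.12, which was 0.44 with no UMI minimum and 0.19 with the highest 8% of doublet scores removed.

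Mesothelial-like cells, which line the pleura, had less of the muscarinic receptor gene Chrm2 in the KO-labelled library, 123 against 36.8 CPM (-1.75, -2.19 to -1.33), with Kcnb2 also lower. Zfp428, Hist1h1e and Rrs1 were highest, with Zfp428 at 23.8 against 96.95 CPM (2.03, 1.64 to 2.42). In cluster 6, Cmss1, Ccn2 and Tsc22d3 were highest and Frmd5, Smim3 and Ifi207 lowest.

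Heat-shock genes stood out across cell types. Their list median lay above the class median in 18 of 18 classes with a value and between 0.24 and 0.99 in the 8 compared classes. The lowest of these, in cluster 6, had an interval that included 0 (-0.03 to 0.44). Hspa8, a constitutive chaperone gene, was 610 against 1167 CPM in AT2-like cells (0.94, 0.91 to 0.96) and 2118 against 4521 CPM in ciliated-like cells (1.09, 1.06 to 1.13). In these classes Hspa8 was chosen after its values were seen, and the list medians there were 0.56 and 0.99. The unfolded protein response list was also above in the compared classes, from 0.16 in ciliated-like to 0.61 in mesothelial-like cells. The cold-induced genes Cirbp and Rbm3, chosen after the heat-shock values were seen, lay below the class median in 8 of 8 compared classes; in AT2-like cells Cirbp was 61.1 against 33.1 CPM. The interval of the Cirbp ratio included 0 in adventitial fibroblast-like cells, venous-like cells and cluster 6. Immediate-early genes, which tissue dissociation induces, had medians of -0.49 in adventitial fibroblast-like cells, -0.59 in cluster 6, -0.19 in mesothelial-like and -0.60 in smooth muscle-like cells, but 0.33 in general capillary-like, 0.22 in ciliated-like and 0.20 in aerocyte-like cells.

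**Figure D4:**
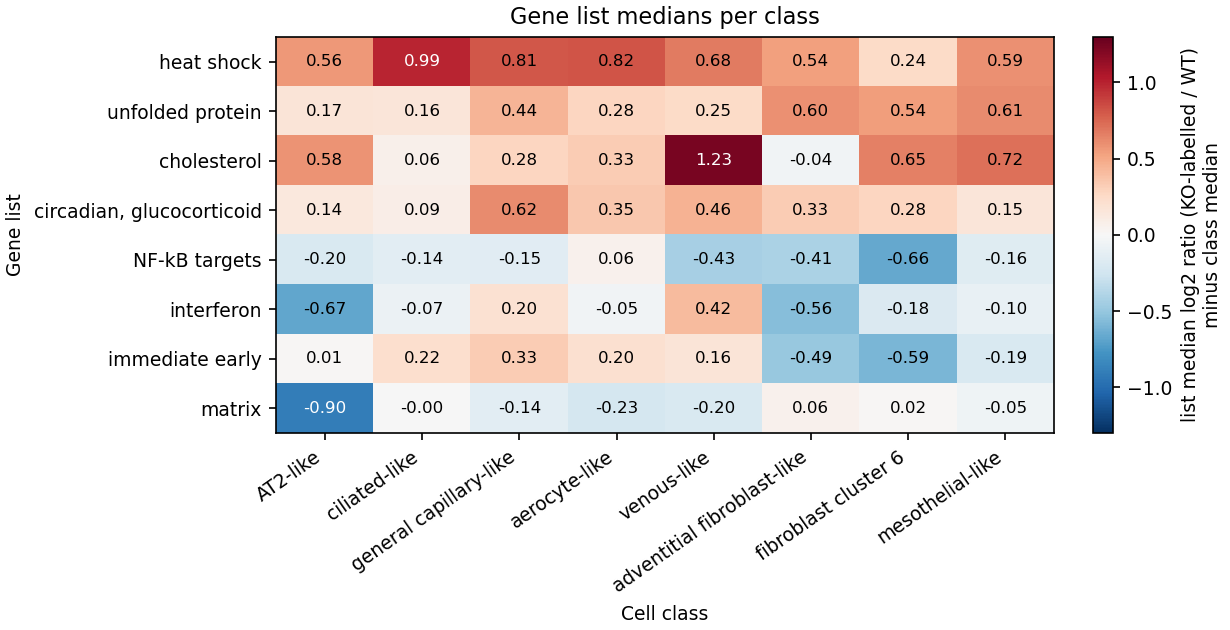
Median log2 ratio (KO-labelled over WT) of 8 gene lists minus the class median, in the 8 compared cell classes, as a colour scale with each value printed. Heat shock lies between 0.24 and 0.99; in AT2-like cells 19 of the 21 measured interferon genes and 29 of the 34 matrix genes were over 10 times higher in another compartment.

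Genes of other cell types were used to look at free RNA. Sftpc in general capillary-like cells was 1508 against 5517 CPM, and Scgb1a1 there 2127 against 194 CPM. Not every class showed these directions, since Scgb1a1 was higher in venous-like cells of the KO-labelled library and Sftpc in adventitial fibroblast-like cells differed by only 0.20. S100a8, a neutrophil gene, was 1.15 against 0.16 CPM in AT2-like cells. Hbb-bs, a haemoglobin gene, had 16 and 1566 UMIs over all cells, 5 and 1561 of them in AT2-like cells, so nearly all of those in the KO-labelled library lay in 1 class and do not show a level of free RNA. Xist had 12 and 8 UMIs and the Y-linked gene Ddx3y 4056 and 2970 UMIs, the pattern of male cells in both libraries.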

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

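In this part the tests on free RNA as the source of Plaur and on genes near the locus were chosen after the result was seen, while the test of Hprt in neutrophil-like cells was written before that value was looked at.

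Plaur had opposite directions in different cell classes under the same comparison. The log2 ratio of the KO-labelled library over the WT library was 2.98 in AT2-like cells and -0.98 in aerocyte-like cells, and the difference between these classes was not tested against replicates. Of the 8 compared classes, 4 had an interval above 0 and 4 an interval below 0. The gap between AT2-like and aerocyte-like cells was 3.97 on the log2 scale. Free RNA from Plaur-rich cells would follow their total, yet Plaur over all cells was lower in the KO-labelled library (-0.51). S100a8 of the Plaur-rich neutrophil-like cells was also lower when counted in AT2-like cells (-2.85, -4.41 to -1.56). This argues against free RNA of neutrophil-like cells as the source of the higher Plaur in AT2-like cells. S100a8 says nothing about RNA of other Plaur-rich classes, such as aerocyte-like cells. For these only the lower total goes against free RNA, so it is not excluded. A biological candidate explanation is that the edited allele makes a transcript with its 3' end intact and its own pattern across cells. Some targeting vectors carry an Hprt minigene, so Hprt from a cassette could be read where the Plaur promoter is active. Hprt in neutrophil-like cells, the class with the most Plaur in the WT library, was 10 and 24 UMIs, with a log2 ratio of 3.13 (2.01 to 4.35), which is consistent with such a cassette but does not identify the allele. T and NK-like cells, with only 11.5 CPM of Plaur in the WT library, also had more Hprt (126.7 against 273 CPM; 1.11, 0.16 to 2.05), and Plaur there was 109 CPM in the KO-labelled library (8 UMIs against 2). That class held 20 cells in the KO-labelled library and its proliferation genes were higher as well (list median 3.47, 7 of 7 members above), so its Hprt does not count clearly for or against a cassette. Across classes of these libraries, which are not independent samples, Spearman's rho between the extra Hprt CPM and the WT Plaur CPM was 0.86 over the 8 compared classes and 0.25 over the 10 classes of 20 to 99 cells. The 8 classes include aerocyte-like and general capillary-like cells, where Hprt was already among the highest genes. The value of 0.86 is therefore not separate support for a cassette.

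Single genes around Plaur differed between the libraries, but whether the edited locus is the cause stays open. The test below uses a median over the genes, which cannot show a change in a few of them. Genes that start within 200 kb deviated from the class median in AT2-like cells by more than 84.4% of matched random lists, which lies between the bounds set for the test. The same figure was 37.2% in general capillary-like cells, 23.8% in ciliated-like cells, 61.8% in mesothelial-like cells and 65.3% in cluster 6. Among them, chosen after their values were seen, Tescl in AT2-like cells had 10 and 148 UMIs (3.31) and Cadm4 53 and 173 UMIs (1.13), while Zfp428 was higher in mesothelial-like cells (2.03) and within counting error in AT2-like cells (0.28, -0.07 to 0.64). Smg9 was lower, at -2.06 in general capillary-like cells (31 and 5 UMIs), -1.99 in mesothelial-like cells (56 and 5 UMIs) and -0.30 in AT2-like cells. In ciliated-like cells Tescl was higher as well (2.22, 1.15 to 3.43) and Smg9 lower (-0.64, -1.32 to -0.005). Pglyrp1 and Apoe, among the genes highest in AT2-like and adventitial fibroblast-like cells of the KO-labelled library, also lie on chromosome 7. They start at 18871331 and 19696109, outside the 200 kb window, and whether their position bears on their values was not tested. A mislabelled library cannot be excluded by Plaur, since the transcript is present in both.

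Immune cells remained after the CD45.2-negative sort, a signal outside the structural cells that were meant to be profiled. They were 5.06% of kept cells in the WT library and 1.51% in the KO-labelled library, among them B and plasma-like, T and NK-like, neutrophil-like and macrophage-like cells. No eosinophil cluster was named.

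A pair of clusters without a class name held enough cells to count. Cluster 18, with mesothelial genes such as Upk3b and Msln beside fibroblast genes such as Dcn and Col1a1, had 166 cells in the WT library and 18 in the KO-labelled library. Cluster 25, with AT2 genes such as Sftpc beside capillary genes such as Cldn5 and Ptprb, had 15 and 73 cells.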

How the results depend on the processing

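The removal of the highest 8% of doublet scores, the equal weighting of classes, the list members left out for free RNA, and the use of classes with 20 to 99 cells were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because there is 1 library per genotype. The contraction list had no pericyte-like or peribronchial fibroblast-like class to be computed in.

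Shares of the 5 compartments kept their direction in 38 of 38 alternatives. With 1000 genes and 10% mitochondrial UMIs as limits the log2 ratio was -0.57 for endothelial and 0.44 for epithelial cells. It was 0.46 for epithelial cells among structural cells alone, and -1.24 for mesothelial cells with marked doublets kept. Of 125 alternatives for the 17 classes 1 reversed, the macrophage-like share, 0.43 with libraries clustered apart.

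Plaur over all cells was -0.26 with TMM factors and 0.40 with classes weighted equally. The first differs by the library scaling. The second differs in several ways at once, since it is a mean of log2 ratios in place of a ratio of pooled counts, gives the 8 compared classes equal weight and leaves out the smaller classes. Thinning to 1000 UMIs turned Plaur in adventitial fibroblast-like cells to 0.19.

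Of 181 alternatives for 17 primary lists, 156 stayed within the counting interval and 26 had the other sign. Thinning gave recruitment values of 0.039 in adventitial, -1.21 in alveolar fibroblast-like and -0.26 in AT2-like cells. It gave 0.054 for contraction and 0.20 for the IL-4 and IL-13 list. Itln1 and Muc5ac, at 0.85 and 0.26, matched values at the floor of 3 UMIs in the KO-labelled library, so these are upper bounds. Clustering apart gave recruitment 0.017 in venous-like and -2.47 in AT2-like cells, plasminogen 0.12 in general capillary-like cells, and surfactant 0.22. A minimum of 100 UMIs gave recruitment -0.54 in venous-like and -0.24 in AT2-like cells, and no minimum 0.44 in smooth muscle-like cells. Without members over 10 times higher elsewhere, recruitment in AT2-like cells was -0.20. TMM factors without centring gave matrix -0.005 in adventitial and 0.12 in alveolar fibroblast-like cells, and contraction -0.34. Doublets kept gave matrix 0.12 and 0.35 in the same order. Removing the highest 8% of doublet scores gave recruitment 0.19 and contraction -0.34 in smooth muscle-like cells, and barrier genes 0.065 in aerocyte-like cells. Means over cells gave contraction -0.021 and the IL-4 and IL-13 list -0.051. Resolution 2 gave contraction -0.39, and the mean of members gave barrier genes -0.15 in general capillary-like cells.

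Of 1372 alternatives for 197 named genes in their class, 1325 kept the sign. Removing the highest 8% of scores turned Ccl2 (1.35) and Ccl7 (0.10) in smooth muscle-like and Timp1 (-0.56) in alveolar fibroblast-like cells, and keeping doublets turned Sftpb in ciliated-like cells (-0.082). Heat shock kept its sign in 177 of 180; it was -0.091 without a UMI minimum and -0.24 without members higher elsewhere in B and plasma-like cells, and -0.11 thinned in smooth muscle-like cells. The reversals of Itln1 and Muc5ac in thinned cells match the floor, and the causes of the others were not tested.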

Other observations

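In this part the tests of free RNA, of a warmer preparation, of the cell mix and of doublets were chosen after the result was seen, and the bounds of the free-RNA test were set before its values were computed but its split by class was made afterwards; the test of ribosomal RNA reads was written before.

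The median of the heat-shock list lay above the class median in 18 of 18 classes with a value. In cluster 6, however, 5 of 13 members lay below the class median and the interval of the list included 0. Some alternatives put the list below the class median in B and plasma-like cells (-0.091 and -0.236) and in smooth muscle-like cells (-0.11). Free RNA from AT2-like cells, scaled by Sftpc, accounted for at most 6.98% of the extra heat-shock CPM in the compared classes other than venous-like and AT2-like cells, under the 20% set as the bound, so it is unlikely to be the main source there. In venous-like cells the figure was 27.6%, between the bounds of 20% and 50%, and the source there stays open. Reads that follow ribosomal RNA were another candidate, since Cmss1 was higher in each of the 8 compared classes (1392 against 3084 CPM in AT2-like cells), but heat-shock UMIs did not follow Cmss1 UMIs from cell to cell. Spearman's rho across AT2-like cells, which are not independent replicates, was -0.071 in 3810 cells of the WT library and -0.052 in 5810 cells of the KO-labelled library. Counts of both were low at 1000 UMIs per cell, which weakens any correlation. A shift between libraries also need not appear from cell to cell within 1 library. This test therefore does not set ribosomal reads aside. A warmer or longer preparation of the KO-labelled library may add to the pattern, but the tables do not decide it. The cold-induced genes Cirbp and Rbm3 lay below the class median in 8 of 8 compared classes, the highest value being -0.14, and 9 of the 16 intervals lay wholly below it. Immediate-early genes, which dissociation induces, were not higher throughout, with medians of -0.59 in cluster 6, -0.60 in smooth muscle-like cells, -0.49 in adventitial fibroblast-like cells and -0.19 in mesothelial-like cells, against 0.33 in general capillary-like, 0.22 in ciliated-like, 0.20 in aerocyte-like, 0.36 in arterial-like and 0.91 in B and plasma-like cells. An effect of the genotype on protein stress would look alike, and with 1 library per genotype it was not tested apart from the preparation.

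Counts of recruitment genes of other cell types in AT2-like cells were lower in the KO-labelled library. Summed over 7 genes, the chemokine genes Ccl2, Ccl4, Ccl5, Ccl7 and Ccl11 and the adhesion genes Vcam1 and Icam2, which another compartment has over 10 times higher, AT2-like cells had 343 and 101 UMIs (log2 ratio -2.34) and ciliated-like cells 77 and 18 UMIs (-1.41). The difference of -0.93 lies between the bounds of 0.5 and 1 in size, so free RNA that follows the cell mix may account for it but was not shown to. With the highest 8% of doublet scores removed in each library, the recruitment list median in AT2-like cells was still -0.86. The main filter had already removed 5.69% of WT cells, so this took out few more there. The test therefore does not decide whether doublets left in the WT library play a part. A biological difference in AT2-like cells stays open and untested.

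Cluster 32, with 8 cells, had cardiac muscle genes such as Myl7 and Tnnt2, and cluster 26 had 61 and 24 immune cells with Gzmb, Ccl3 and Ccl4.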
